A study of Mus musculus with 5 samples.

How the data were processed

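Reduced representation bisulfite sequencing of mouse ES cells was taken from 5 tables, 1 each for WT, Fbxl10 T/T, Ring1B -/-, Eed -/- and Ezh2 -/-. Per the labels' extract protocol, genomic DNA was cut with MspI, fitted with indexed adapters, pooled, size-selected and converted with bisulfite, and CpG-methylated DNA made in vitro was added as an internal control. Per the submitters' processing notes, BSMAP 2.74 and the mouse build mm9 were used, and trimming, removal of duplicates and depth filters are not stated there. Per the file headers, each row of a table is 1 cytosine with its position, strand, sequence context, ratio and read numbers, and the column names are those of the methylation script of BSMAP.

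The deposited counts are raw counts of reads per cytosine: reads that show C, reads that show C or T, and reads of the opposite strand, per the file headers. The deposited expected counts are reads that show C or T scaled by the authors for C-to-T variants read on the opposite strand, and they need not be whole. The deposited fraction is the reads that show C over these expected counts, capped at 1, per the file headers and as checked from the values. CpGs are listed on the + strand only, so both strands had been summed before deposit. At 7 cytosines of the WT table the count stood at 65535, the largest a 16-bit number can hold.

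Groups followed the genotype labels, with 1 library per group, and each mutant was compared with WT. The main values used the raw counts, as reads showing C over reads showing C or T, at CpGs with at least 10 reads in each library compared, on the 19 autosomes and the X chromosome. The tables listed 989737 CpGs in WT, 936729 in Fbxl10 T/T, 467356 in Ring1B -/-, 481496 in Eed -/- and 458066 in Ezh2 -/-. At 10 reads a single CpG resolves steps of 10 percentage points, and the windows tested without MspI-site CpGs held a median of 478 reads in Fbxl10 T/T, 75 in Ring1B -/-, 77 in Eed -/- and 72 in Ezh2 -/-.

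Single CpGs were tested with Fisher's exact test (two-sided) on the reads of the 2 libraries and adjusted by Benjamini-Hochberg over the CpGs tested, and called at an adjusted p under 0.05 with a difference of at least 25 percentage points. Regions were consecutive windows of 1000 bases with at least 5 CpGs at 10 reads in both libraries. Their level is the mean over CpGs, and they were called at a difference of at least 20 points with an adjusted p under 0.05 from Fisher's exact test on summed reads. Reads within a window are not independent, so these p-values rank windows of the 2 libraries and carry no spread between cultures. Read totals are sums of the counts per CpG, so a read that covers several CpGs is counted at each of them. Intervals are 95% Wilson intervals on these counts, or on numbers of windows where a share of windows is given. They take the counts as independent and are therefore too narrow where reads or neighbouring windows are related. The windows stood in for promoters, as laid down before the data were examined for the case that the annotation given does not share the build of the tables. The annotation at hand was of build GRCm38, no coordinates were moved between builds, and therefore the promoters, the targeted genes, the 13 fixed gene lists and the classes of genomic elements were not analysed here, and no gene name is given. The rule for naming windows was fixed at the same time: per mutant, the 12 called windows with the largest rise and the 8 with the largest fall. For these, the longest stretch of sequence that the overlapping 5-base contexts of the tables spell out was written for the 3 largest in each direction in Fbxl10 T/T.

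Other choices were made after the data were seen. CpGs inside CCGG were left out in a second setting, together with a minimum of 5 reads in another. In a further one the reads were summed over windows with at least 5 CpGs of at least 1 read and at least 30 reads in each library. Also chosen then were the classes by WT level (edges 10, 30 and 70%), the clusters of risen windows (gaps of at most 20 kb, 1000 random reassignments), the comparison of mutants with each other and the read depth per chromosome. To read the Fbxl10 T/T gains in other mutants, 10000 random lists were drawn, matched on mean methylation in 10 bins. All comparisons share 1 WT library, so for the overlaps its reads at each CpG were also divided at random into 2 sets, 1 for each comparison, 20 times, and medians over the divisions are given. The alternatives fixed beforehand were minimums of 5 and 20 reads, a cap at the 99.9 percentile of reads, CpGs covered in all 5 libraries only, thinning to 10 reads, autosomes only, other size thresholds, at least 3 or 10 CpGs, windows of 2 kb, read-weighted means and subtraction of the median difference.

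The tests were run on simulated data first, with reads drawn for the real CpGs at their real depth and 200 windows changed per comparison, 50 at each of 4 sizes. Of windows raised by 30 points, 98% were called in Fbxl10 T/T, 98% in Ring1B -/-, 94% in Eed -/- and 98% in Ezh2 -/-. Of those raised by 40 points all were called, and of those raised by 20 points 50%, 44%, 48% and 60%. None of 27423, 1772, 2055 and 1350 unchanged windows was called, and of unchanged CpGs 5 of 624650, 3 of 30233, 4 of 32210 and 2 of 24172 were. These draws hold counting error only.

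Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The intervals given in the tables and the reads of chromosome Y entered no comparison. A check of strand against strand within a library was not run, since the strands of CpGs were summed in the tables.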

Results

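DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in 5 libraries of mouse embryonic stem (ES) cells, 1 library for each of 5 genotypes. In RRBS the enzyme MspI cuts genomic DNA at CCGG, short fragments rich in CpG are kept, and bisulfite converts unmethylated cytosines, so that the share of reads that still show a cytosine at a CpG is its methylation level. The genotypes were WT, Fbxl10 T/T, Ring1B -/-, Eed -/- and Ezh2 -/-. FBXL10 is a chromatin protein that binds unmethylated CpG-rich DNA, Ring1B is the ubiquitin ligase of Polycomb repressive complex 1, and Eed and Ezh2 are core members of Polycomb repressive complex 2. The title of the series asks whether FBXL10 protects Polycomb-bound genes from gaining methylation, which sets Fbxl10 T/T against WT and the 3 Polycomb mutants beside it. WT and Fbxl10 T/T carry the same strain label (C57BL/6J), the same description of culture on feeder cells and passage 17, whereas the 3 Polycomb mutants have another culture description and no strain or passage label.

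The WT library held 43079673 reads at CpGs and the Fbxl10 T/T library 27338258, with a median of 33 and 23 reads per listed CpG. In these and all later totals a read is counted at each CpG that it covers. The Ring1B -/-, Eed -/- and Ezh2 -/- libraries were shallower, with 1859713, 1942248 and 1766681 reads at CpGs and a median of 3 reads per CpG in each. On the autosomes and the X chromosome, 689714 CpGs reached the minimum of 10 reads in WT and 634003 in Fbxl10 T/T, against 32080 in Ring1B -/-, 34229 in Eed -/- and 25970 in Ezh2 -/-. There was 1 library per genotype, so no difference below has a replicate check, and every Fisher's exact test compares the reads of 2 libraries and not 2 genotypes. All intervals (95%, Wilson) cover counting error only, and they take the counts at neighbouring CpGs as independent, which makes them too narrow. Regions are given as 1-kb windows in mm9 coordinates, counted from 1, without gene names, because no annotation of that build was used here.

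Methylation of the covered CpGs was higher in Fbxl10 T/T than in WT. Over all reads at CpGs with at least 10 reads, 31.9% were methylated in Fbxl10 T/T (95% interval 31.86 to 31.9%) and 26.5% in WT (26.51 to 26.53%). The level was 24.6% in Ring1B -/- (24.5 to 24.7%), 23.2% in Eed -/- (23.1 to 23.3%) and 20.5% in Ezh2 -/- (20.4 to 20.7%), over far fewer CpGs. CpGs inside the MspI recognition site read higher than their neighbours in every library, so each level is also given without them, a setting chosen after the data were seen. Then the level was 20.6% in Fbxl10 T/T, 13.3% in WT, 11.9% in Ring1B -/-, 11.5% in Eed -/- and 9.42% in Ezh2 -/-. In the 5035 CpGs that reached 10 reads in all 5 libraries, WT read 18.99%, below Ring1B -/- (25.8%), Eed -/- (26.4%) and Ezh2 -/- (22.6%), while Fbxl10 T/T read 30.7%. The order of WT and the 3 Polycomb mutants thus depended on which CpGs were counted, and Fbxl10 T/T was highest in each of these settings. At a minimum of 20 reads, Ring1B -/- (32.3%) and Eed -/- (31.4%) stood above Fbxl10 T/T (31.0%), again over other CpGs in each library.

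In Fbxl10 T/T, 6050 of 27623 windows rose against WT (21.9%) and 2040 fell (7.39%). A window was tested when at least 5 of its CpGs had 10 reads in both libraries, and called when its mean over CpGs differed by at least 20 percentage points with an adjusted p under 0.05 (Fisher's exact test on summed reads, two-sided, Benjamini-Hochberg adjustment over the windows tested). Mean levels of the tested windows were 31.1% in WT and 37.9% in Fbxl10 T/T. Of 628587 CpGs tested singly, 87263 rose (13.9%) and 41555 fell (6.61%) by at least 25 points. Without MspI-site CpGs, 4328 of 17192 windows rose and 286 fell. With at least 3 CpGs in place of 5, which admits windows with fewer CpGs, 7870 of 53931 windows rose and 9984 fell, so that the balance of gains and losses turned with the windows admitted.

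Gains lay both in windows that were nearly unmethylated in WT and in windows of intermediate methylation, and most of the nearly unmethylated ones did not rise. With MspI-site CpGs kept, 1818 of the 6050 gains started below 10% in WT. Of 14323 windows below 10% in WT, counted without MspI-site CpGs, 2980 rose in Fbxl10 T/T (20.8%), from a median of 3.397% to a median of 57.5%, with quartiles of 46.0% and 65.8%. Another 10520 of them (73.4%) stayed within 5 points of WT, and 712 (4.97%) rose by 5 to 20 points. Among the 2980 risen windows, 2030 stood above 50% in Fbxl10 T/T. The share that rose was larger among windows of intermediate methylation: of 1437 windows at 10 to 30% in WT, 1056 were called up (73.5%), and their mean went from 16.7% to 49.9%, while of 584 windows at 30 to 70%, 291 were called up and 34 down. Windows methylated in WT moved the other way. Of 848 windows at 70% or above, 240 were called down (28.3%) and 1 up, with means of 86.6% in WT and 74.5% in Fbxl10 T/T. These classes are set by the WT level itself, so counting error in WT pushes the lowest class up and the highest class down, although the tested windows held a median of 787 WT reads.

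**Figure D1:**
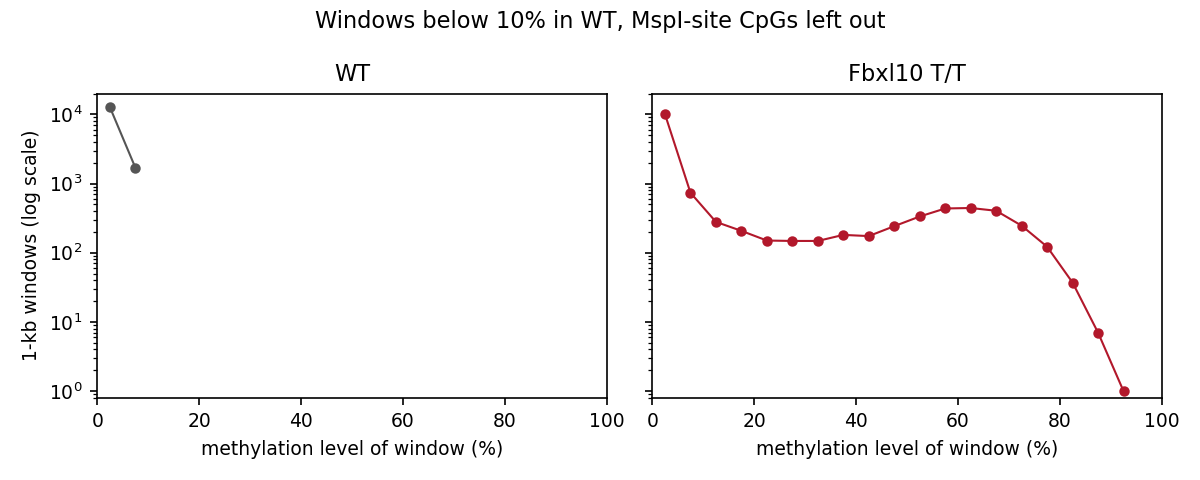
Methylation level of the 14323 1-kb windows below 10% in WT, MspI-site CpGs left out, in WT and in Fbxl10 T/T. The x axis is the level of a window in percent, and the y axis the number of windows per 5-point bin on a log scale. In Fbxl10 T/T, 10028 windows lie below 5% and a separate hump peaks with 443 windows between 60 and 65%.

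Windows that rose were slightly less common where CpGs were densest. Among windows below 10% in WT, 23.1% rose where fewer than 20 CpGs were listed (95% interval 21.8 to 24.5%), 21.3% with 20 to 39 CpGs (20.3 to 22.4%), 19.6% with 40 to 59 (18.2 to 21.2%) and 15.6% with 60 or more (14.0 to 17.4%). These intervals are on numbers of windows taken as independent, although some risen windows were neighbours. The level reached by the risen windows hardly differed, with medians from 57.02% to 59.03% over the 4 density classes. By chromosome the share that rose ran from 14.4% on chromosome 10 (102 of 708 windows) to 26.5% on chromosome 6 (181 of 683). On the X chromosome 47 of 270 windows rose (17.4%).

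Many risen windows stood alone, and some sat together in clusters more often than after random reassignment of the calls. Joined over gaps of at most 20 kb, the 2980 windows made 2070 groups, of which 1443 were single windows and 21 held 5 or more, with 132 windows in all. When the calls were reassigned at random among the 14323 windows 1000 times, the median number of groups of 5 or more was 1 and the most was 5. This reassignment takes neighbouring windows as independent, so it cannot tell clusters from likeness of adjoining windows. Some clusters were short, such as 5 risen windows in 5 kb on chromosome 15, 74346001 to 74351000. In each cluster that follows, only windows below 10% in WT are counted. Each span runs from the first to the last risen window, and levels are over the risen windows. The largest cluster spanned chromosome 11, 96133001 to 96216000, where 13 of 17 such windows rose, from 2.79% of 11615 reads in WT (2.51 to 3.10%) to 53.2% of 5427 reads in Fbxl10 T/T (51.8 to 54.5%). On chromosome 2, 74493001 to 74543000, all 11 such windows rose, from 4.71% (4.35 to 5.10%) to 48.1% (46.8 to 49.5%). On chromosome 7, 86642001 to 86689000, all 10 rose, from 5.49% (5.04 to 5.96%) to 57.9% (56.5 to 59.3%). On chromosome 6, 52167001 to 52197000, 8 of 9 rose, from 4.72% (4.22 to 5.28%) to 68.5% (67.1 to 69.9%).

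**Figure D2:**
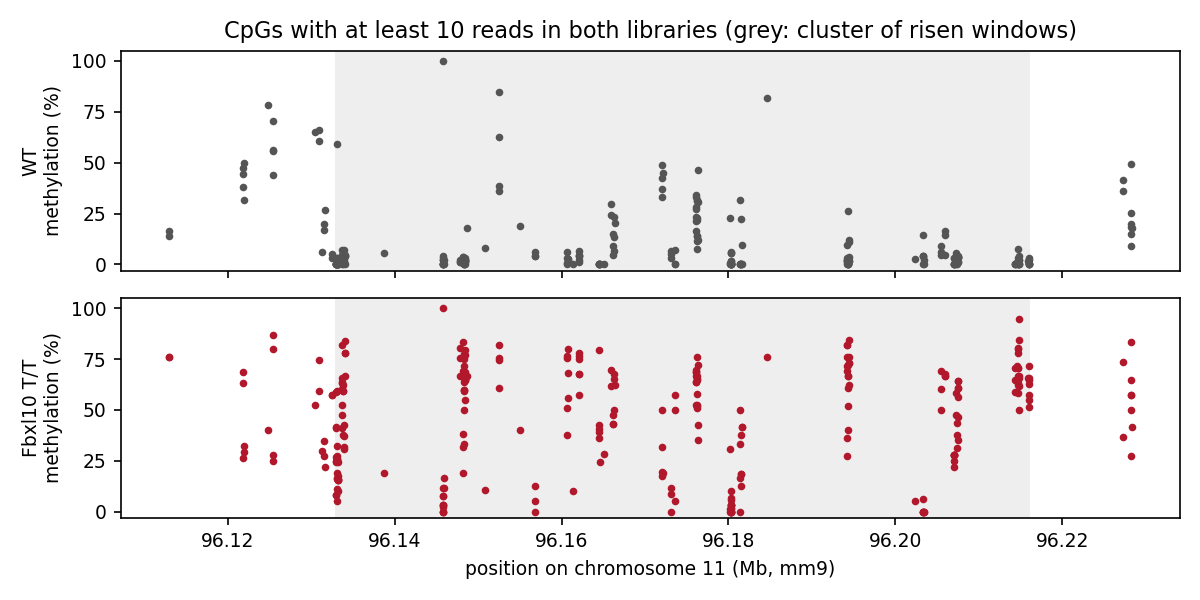
Methylation of single CpGs around the largest cluster of risen windows, chromosome 11, 96133001 to 96216000 (mm9), drawn with 20 kb on each side. The x axis is the position in Mb, the y axis the methylation level in percent, each point is 1 of the 291 CpGs outside MspI sites with at least 10 reads in both libraries, and grey marks the cluster. Over the 13 risen windows, 2.79% of reads were methylated in WT and 53.2% in Fbxl10 T/T.

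The 12 windows with the largest gains rose by 75.8 to 82.7 points, from 2.55 to 13.4% in WT to 81.5 to 89.2% in Fbxl10 T/T, on 8 chromosomes. The largest was chromosome 18, 36177001 to 36178000, at 5.70% in WT (SD over its 12 CpGs 6.61, 452 reads) and 88.4% in Fbxl10 T/T (SD 2.53, 242 reads), with an adjusted p of 1.33e-105 by Fisher's exact test. Its longest stretch readable from the sequence contexts in the tables, at 36177885 to 36177911, is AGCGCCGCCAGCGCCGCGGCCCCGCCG. The adjoining window from 36178001 to 36179000 rose from 2.86% to 81.5% over 15 CpGs. On chromosome 4, the window from 146316001 to 146317000 rose from 8.49% (868 reads) to 87.7% (348 reads). It holds, at 146316432 to 146316503, the stretch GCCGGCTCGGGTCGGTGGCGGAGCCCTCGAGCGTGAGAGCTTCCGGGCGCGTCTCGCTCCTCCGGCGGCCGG. On the X chromosome, the window from 98893001 to 98894000 rose from 5.53% (128 reads) to 88.1% (81 reads). Others among the 12 lay on chromosome 8 at 112486001, 73118001 and 107792001, on chromosome 14 at 49275001, on chromosome 6 at 29424001, on chromosome 17 at 72131001 and 35576001, and on chromosome 5 at 144014001. Of these 12 windows 8 also kept 5 CpGs without MspI sites, and in all 8 the gain was then at least 20 points.

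The 8 windows with the largest losses changed by -72.2 to -65.7 points, from 78.6 to 91.9% in WT to 8.11 to 26.1% in Fbxl10 T/T. On chromosome 4, the window from 149330001 to 149331000 fell from 80.3% (SD over its 6 CpGs 7.83, 329 reads) to 8.11% (SD 10.05, 250 reads), with an adjusted p of 1.45e-64 by Fisher's exact test. At 149330325 to 149330365 it holds the stretch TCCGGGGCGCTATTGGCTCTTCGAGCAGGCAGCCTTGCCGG. On chromosome 5, the window from 65739001 to 65740000 fell from 89.4% to 20.9%, and on chromosome 6 the window from 53971001 to 53972000 fell from 81.2% to 14.0%. Others lay on chromosome 8 at 5587001, on chromosome 10 at 61990001, on chromosome 11 at 100353001, on chromosome 18 at 57189001 and on chromosome 5 at 135515001. Only the chromosome 6 window kept 5 CpGs without MspI sites, where it fell by 70.2 points.

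In Ring1B -/-, few of the covered windows differed from WT. Of 1972 windows tested 26 rose (1.32%) and 11 fell (0.558%), with mean levels of 9.35% in WT and 13.1% in Ring1B -/-. The largest gain was on chromosome 5, 144016001 to 144017000, from 9.94% in WT (652 reads) to 78.7% in Ring1B -/- (52 reads), with an adjusted p of 1.57e-24 by Fisher's exact test. Chromosome 19, 11943001 to 11944000, rose from 11.1% to 68.4%, chromosome 2, 28765001 to 28766000, from 18.4% to 62.5%, and chromosome 7, 7252001 to 7253000, from 10.2% (2333 reads) to 54.4% (607 reads). At a minimum of 5 reads the rise on chromosome 19 was of 35.2 points in place of 57.3. The largest losses were on chromosome 14, 27909001 to 27910000, from 84.5% to 37.0%, and on chromosome 11, 117641001 to 117642000, from 61.5% to 17.3%. The latter changed by only -18.0 points at a minimum of 5 reads, where its call was lost, and by -22.9 points with all reads outside MspI sites summed. The other named windows that rose did so by 25.7 to 37.2 points, and those that fell did so by less (-39.5 to -23.6 points). At a minimum of 5 reads, 2 of these 8 rises lost their call, chromosome 14, 57396001 (8.79 points), and chromosome 13, 34094001 (15.3 points), and 3 of these 6 falls did (-19.3 to -18.6 points). With all reads outside MspI sites summed, the rises on chromosome 9, 55056001 (16.3 points), chromosome 14, 57396001 (19.5 points), and chromosome 13, 34094001 (13.5 points), lost their call. All windows together were shifted by a median of 3.37 points, and after subtracting it 17 rose and 13 fell. Without MspI-site CpGs the median difference was 0, and 8 of 1073 windows rose and 4 fell.

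In Eed -/-, 18 of 2255 windows rose (0.798%) and 13 fell (0.576%). Chromosome 7, 7252001 to 7253000, gained most, from 10.2% in WT to 60.6% in Eed -/- (689 reads, adjusted p = 1.42e-139 by Fisher's exact test), and chromosome 19, 11943001 to 11944000, rose from 13.9% to 45.0% over its 7 CpGs, so that 2 of the largest gains of Ring1B -/- were also the 2 largest in Eed -/-. At a minimum of 5 reads the chromosome 19 window lost its call in Eed -/-, with a rise of 17.3 points, or 14.7 points without MspI-site CpGs. Both comparisons share the 1 WT library and its chance values. The largest losses were on chromosome 16, 22928001 to 22929000, from 89.9% (790 reads) to 36.4% (55 reads), and on chromosome 13, 120277001 to 120278000, from 60.5% to 10%. The other 10 named windows that rose did so by 22.6 to 30.5 points, and the other 6 that fell changed by -49.0 to -28.8 points. At a minimum of 5 reads, 8 of these 10 rises lost their call, with 6.68 to 17.9 points left, while all 8 named falls kept theirs. With all reads outside MspI sites summed, 9 of the 10 rises were measured and 7 lost their call, with 1.11 to 15.9 points left. After subtracting the median difference of 2.72 points, 11 windows rose and 15 fell, which reverses the balance. Without MspI-site CpGs the median difference was 0, and 7 of 1221 windows rose and 4 fell. In the 10520 windows that stayed low in Fbxl10 T/T, MspI-site CpGs read 35.4% in Ring1B -/-, 34.0% in Eed -/- and 32.6% in Ezh2 -/-, against 22.1% in WT. Gains counted with these CpGs can include this gap in all 3 mutants. In Eed -/- all 5 CpGs of the named rise on chromosome 12, 111976001, lay at MspI sites.

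In Ezh2 -/-, 9 of 1550 windows rose (0.581%) and 10 fell (0.645%). Chromosome 11, 5421001 to 5422000, rose from 6.15% (315 reads) to 47.7% (52 reads), with an adjusted p of 5.75e-12 by Fisher's exact test, and the other 8 gains were of 20.03 to 27.1 points. Chromosome 6, 89645001 to 89646000, fell from 96.1% (258 reads) to 42.0% (150 reads), with an adjusted p of 4.65e-33, and chromosome 1, 119994001 to 119995000, fell from 89.0% to 47.8% (617 reads). The same window on chromosome 6 and the one on chromosome 16 at 22928001 were among the 8 largest losses in Eed -/- as well. After subtracting the median difference of 2.52 points, 6 windows rose and 12 fell, and without MspI-site CpGs none of 744 rose and 5 fell. In Ezh2 -/- none of the 9 gains could be measured over 5 CpGs without MspI sites at 10 reads. With all reads outside MspI sites summed, 8 of the 9 were measured: chromosome 11, 5421001, kept its call with a rise of 24.0 points, 6 lost theirs with rises of 0.773 to 15.6 points, and chromosome 19, 42165001, changed by -13.5 points. The gain at chromosome 19, 42165001 to 42166000, became a difference of -4.29 points at a minimum of 5 reads, where 3 others lost their call (6.26 to 14.5 points).

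Among single CpGs, the balance of gains and losses in Ring1B -/- and Eed -/- depended on the CpGs admitted, while in Ezh2 -/- losses were more frequent than gains. In Ring1B -/- 361 of 31708 CpGs rose and 406 fell, in Eed -/- 170 of 33699 rose and 239 fell, and in Ezh2 -/- 128 of 25601 rose and 336 fell. At a minimum of 20 reads, 87 rose and 57 fell in Ring1B -/-, 66 rose and 39 fell in Eed -/-, and 26 rose and 51 fell in Ezh2 -/-. In CpGs covered in all 5 libraries, 129 rose and 106 fell in Ring1B -/-, 82 rose and 71 fell in Eed -/-, and 72 rose and 119 fell in Ezh2 -/-. Without MspI-site CpGs losses prevailed, with 137 up and 353 down in Ring1B -/-, 61 up and 202 down in Eed -/-, and 29 up and 274 down in Ezh2 -/-. Thinned to 10 reads per CpG in both libraries, which lowers the power of the test at every deeper CpG, 4 rose and 5 fell in Ring1B -/-, 3 rose and 10 fell in Eed -/-, and none rose or fell in Ezh2 -/-. In Fbxl10 T/T the same thinning left 12604 CpGs up and 1970 down.

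To read more windows in the shallow libraries, all reads outside MspI sites were also summed over windows with at least 5 CpGs and at least 30 reads in each library, a setting chosen after the data were seen. Windows below 10% in WT then stayed low: 61 of 8191 rose in Ring1B -/- (0.745%), 24 of 8570 in Eed -/- (0.280%) and 11 of 8064 in Ezh2 -/- (0.136%), against 3398 of 15931 in Fbxl10 T/T (21.3%). Windows at 30 to 70% in WT fell by a median of 20.5 points in Ezh2 -/- (33 of 70 called down) and by a median of 15.7 points in Eed -/- (31 of 79), and their median changed by -2.39 points in Ring1B -/- (18 of 77 down, 11 up). In Fbxl10 T/T the same class changed by a median of 17.9 points upward, with 432 of 946 windows up. Windows at 70% or above fell in all 4 mutants, by medians of 16.1 points in Ring1B -/- (21 of 46 down), 12.9 points in Eed -/- (18 of 59), 18.8 points in Ezh2 -/- (25 of 55) and 10.4 points in Fbxl10 T/T (444 of 1428). The classes are set by the level in the 1 WT library that all 4 comparisons share, which favours a fall in the highest class of each. The shallow libraries admit only a small part of the methylated windows that Fbxl10 T/T admits, so these medians are over different windows.

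The windows that gained methylation in Fbxl10 T/T were then read in the Polycomb mutants. Over the 2980 windows that rose from below 10%, 48.2% of reads were methylated in Fbxl10 T/T (95% interval 48.1 to 48.2%) and 3.54% in WT (3.52 to 3.56%), against 4.28% in Ring1B -/- (4.18 to 4.38%), 3.45% in Eed -/- (3.36 to 3.54%) and 3.62% in Ezh2 -/- (3.52 to 3.72%). In the 10520 windows that had stayed within 5 points, the levels were 1.60% in WT, 1.66% in Fbxl10 T/T, 3.15% in Ring1B -/-, 2.93% in Eed -/- and 2.41% in Ezh2 -/-. Among risen windows with at least 30 reads, 46 of 1555 stood at 20% or more in Ring1B -/- (2.96%), 8 of 1644 in Eed -/- (0.487%) and 14 of 1512 in Ezh2 -/- (0.926%). Among the windows that had stayed within 5 points, the same count was 46 of 6300 in Ring1B -/- (0.730%), 24 of 6571 in Eed -/- (0.365%) and 23 of 6216 in Ezh2 -/- (0.370%). In the largest cluster, on chromosome 11, the levels were 6.90% in Ring1B -/- (464 reads, 4.93 to 9.57%), 6.73% in Eed -/- (490 reads, 4.84 to 9.31%) and 7.96% in Ezh2 -/- (490 reads, 5.88 to 10.7%). Each of these is above WT (2.79%) and far below Fbxl10 T/T (53.2%). In the chromosome 7 cluster all 3 also read above WT (5.49%), with 10.1% in Ring1B -/- (7.44 to 13.4%), 10.9% in Eed -/- (8.33 to 14.2%) and 12.5% in Ezh2 -/- (9.21 to 16.8%). The cluster levels are not corrected for background. Cytosines outside CpG read 2.62% in Ring1B -/-, 2.83% in Eed -/- and 2.10% in Ezh2 -/-, against 1.02% in WT. The cluster windows were also chosen as below 10% in this same WT library. How much of the differences from WT is methylation was not tested. In the chromosome 6 cluster, Ring1B -/- (1.74%, 0.678 to 4.39%) and Ezh2 -/- (4.10%, 1.76 to 9.24%) read below WT (4.72%) and Eed -/- above it (6.48%, 4.28 to 9.70%). In the chromosome 2 cluster, Ring1B -/- read 4.46% (2.84 to 6.93%), Eed -/- 5.83% (3.95 to 8.52%) and Ezh2 -/- 7.03% (4.84 to 10.1%), against 4.71% in WT.

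**Figure D3:**
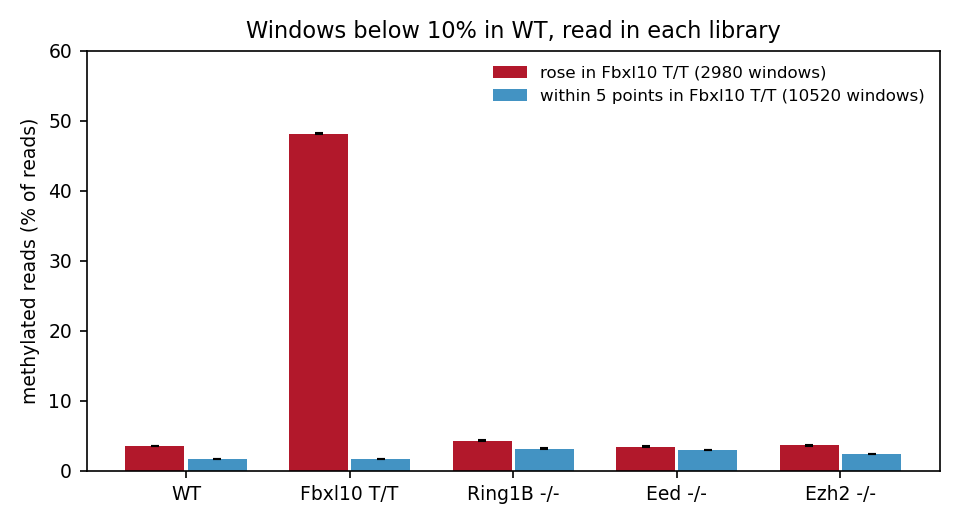
Methylated reads in percent of reads (y axis) in each of the 5 libraries (x axis), over the 2980 windows below 10% in WT that rose in Fbxl10 T/T and the 10520 that stayed within 5 points. Bars are read-weighted levels with 95% Wilson intervals, MspI-site CpGs left out. The risen windows read 48.2% in Fbxl10 T/T and from 3.45 to 4.28% in the 3 Polycomb mutants.

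In the window test on all CpGs, 376 of the Fbxl10 T/T gains were measured in Ring1B -/-, 415 in Eed -/- and 258 in Ezh2 -/-. Their median difference from WT was 2.61 points in Ring1B -/-, 1.51 points in Eed -/- and 2.20 points in Ezh2 -/-, while the same windows rose in Fbxl10 T/T by medians of 48.6, 49.3 and 49.5 points. Each median lay at or below the 0.01 percentile of 10000 random lists of windows matched on mean methylation, which describes these libraries and is no test across windows. The lists had medians of 3.54, 3.30 and 3.26 points, and the windows that were not Fbxl10 T/T gains 3.62, 2.99 and 2.59 points. Where matching counts the mutant's own level, it favours windows that are high there by counting error. The percentiles therefore cannot show that the gains were unusually low in the Polycomb mutants. Without MspI-site CpGs the medians of the Fbxl10 T/T gains were -0.513, -0.758 and -0.389 points, the last with a 95% interval from order statistics that includes 0 (-0.817 to 0.528). Windows called up in both numbered 10 for Ring1B -/- (4.96 for independent lists), 4 for Eed -/- (3.31) and 0 for Ezh2 -/- (1.498). In the setting with summed reads, 78 of the 113 gains of Ring1B -/- were also gains of Fbxl10 T/T, where independent lists give 24.2, against 10 of 32 in Eed -/- (7.05) and 8 of 18 in Ezh2 -/- (3.85). Both comparisons of each pair use the WT library. With its reads at each CpG divided at random into 2 sets, 1 for each comparison, the shared gains were 75 in Ring1B -/- (73 to 79 over 20 divisions, 23.7 for independent lists), 10 in Eed -/- (7 to 12, 7.05) and 8 in Ezh2 -/- (6 to 11, 3.84). This takes out counting error shared through WT, and not what is particular to that 1 culture. Independent lists also take no account of the WT level. With summed reads, 73.1% of windows at 10 to 30% in WT rose in Fbxl10 T/T, against 21.3% of those below 10%. Of the 113 gains of Ring1B -/-, 41 lay at 10 to 30% in WT, as did 6 of 32 in Eed -/- and 6 of 18 in Ezh2 -/-. Lists matched on WT level would share more windows, and how many was not tested.

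As scales for these counts, the Polycomb mutants were compared with each other by the same test. Eed -/- against Ring1B -/- gave 3 windows up and 5 down of 629 (0.477 and 0.795%). Ezh2 -/- against Ring1B -/- gave none up and 9 down of 386 (2.33%), and Ezh2 -/- against Eed -/- gave 1 up and 4 down of 441 (0.227 and 0.907%). The shares down lie above those of the mutants against WT (0.558 to 0.645%), and the shares up below them (0.581 to 1.32%). Both sides of these pairs held medians of 72 to 80 reads per window, against 793.5 to 823 in WT, so the power is lower here.

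Cytosines outside CpG read low in all libraries. They were at 1.02% in WT and 0.688% in Fbxl10 T/T, and at 2.62% in Ring1B -/-, 2.83% in Eed -/- and 2.10% in Ezh2 -/-. In WT, cytosines followed by A read 1.85% and those followed by T 0.699%, and in Fbxl10 T/T 0.967% and 0.486%. The 3 Polycomb mutants showed no such gap in the same direction and size: A-followed cytosines read 2.41% and T-followed ones 2.67% in Ring1B -/-, 2.93% and 2.73% in Eed -/-, and 2.08% and 1.97% in Ezh2 -/-. On the mitochondrial genome, cytosines outside CpG read from 0.105% in Fbxl10 T/T to 2.01% in Eed -/-. These levels are upper limits for incomplete conversion.

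Read depth per chromosome was level on most autosomes of Fbxl10 T/T, Ring1B -/- and Eed -/- and raised on a few of them, and it was uneven on most autosomes in Ezh2 -/-. Against WT, after scaling each library to the median of its autosomes, the ratio was 1.37 on chromosome 6 in Fbxl10 T/T, where the next autosome stayed within 1.1 of the median. It was 1.58 on chromosome 8 in Ring1B -/-, 1.36, 1.40 and 1.495 on chromosomes 3, 6 and 8 in Eed -/-, and 1.21 on chromosome 3 in Ezh2 -/-, where only 3 autosomes lay within 1.1 of the median and 51.6% of the 5-Mb bins of chromosome 3 were raised. In Ezh2 -/-, chromosomes 9, 18, 8, 11 and 15 stood close behind chromosome 3 (1.19, 1.19, 1.18, 1.17 and 1.17). Without the CpGs of highest depth, chromosomes 1, 3, 8, 9, 11, 13, 15, 16 and 18 of Ezh2 -/- read 1.21 to 1.30. The other autosomes then read 0.914 to 1. Leaving out chromosome 6, 2799 of the low windows rose in Fbxl10 T/T (20.5%).

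**Figure D4:**
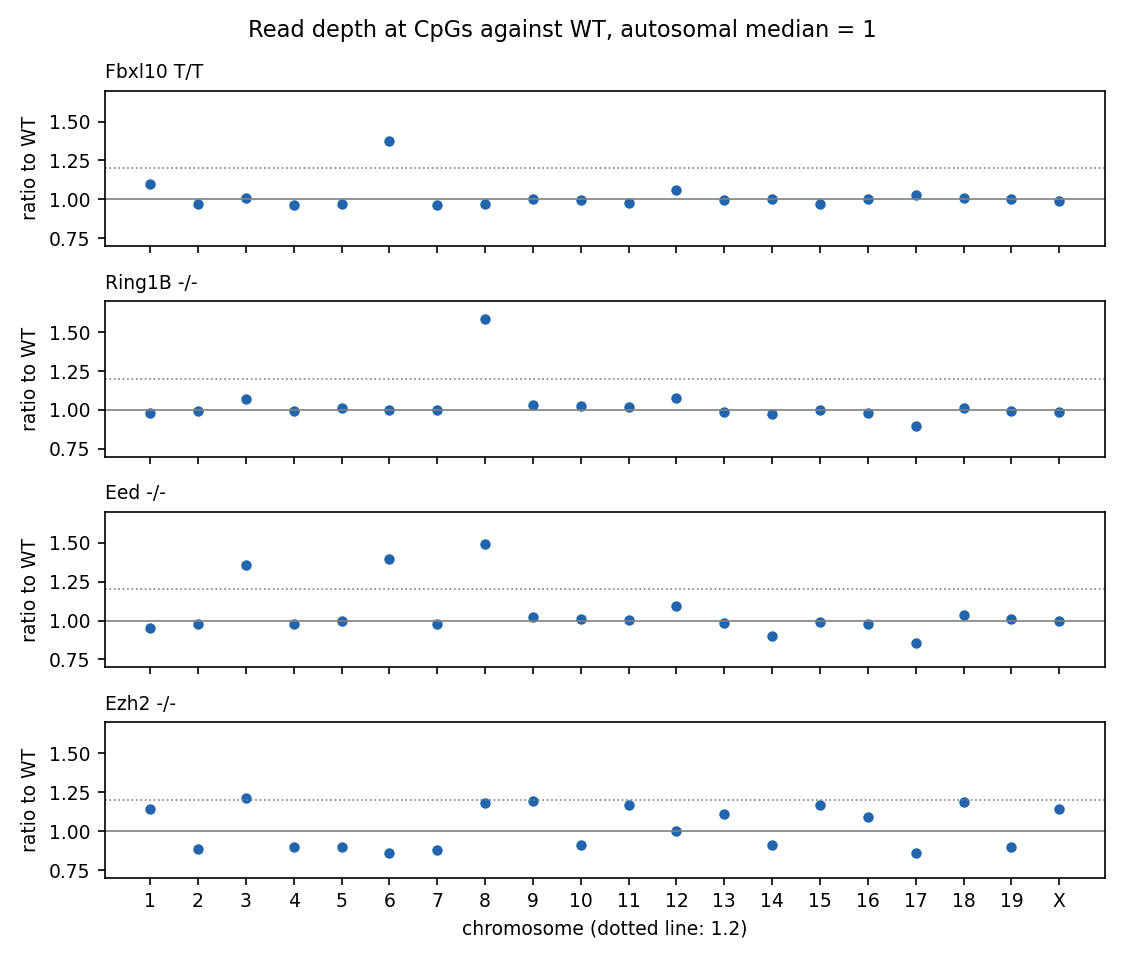
Reads per chromosome in each mutant library against WT (y axis), scaled to the median of the autosomes, for the 19 autosomes and X (x axis). Chromosome 6 stands at 1.37 in Fbxl10 T/T, chromosome 8 at 1.58 in Ring1B -/- and at 1.495 in Eed -/-.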

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

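Chosen after the results were seen were all tests below except those of density bias, local amplification and extra copies over all 6 flagged chromosomes, and that of a read-end effect at MspI sites.

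Read depth of chromosomes, a signal that no comparison of the report uses, stood more than 1.2 times above WT in 6 cases. These were chromosome 6 in Fbxl10 T/T (1.37), chromosome 8 in Ring1B -/- (1.58), chromosomes 3, 6 and 8 in Eed -/- (1.36, 1.40 and 1.495) and chromosome 3 in Ezh2 -/- (1.21). Over all 6, neither bias against CpG density (lowest ratio in CpG-poor or CpG-dense windows 1.17), local amplification (lowest share of 5-Mb bins with raised depth 51.6%) nor extra copies of the chromosome (highest ratio 1.58) could be decided, because in Ezh2 -/- only 3 autosomes lie within 1.1 of the median. With Ezh2 -/- left out, density bias does not account for the other 5 (lowest ratio 1.32, or 1.25 less 1 SD), nor does local amplification (lowest share of bins 86.7%). Extra copies of these chromosomes in some or all cells, with a highest ratio of 1.58, remain the likely source, as a hypothesis, and whether they arose in culture was not tested.

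CpGs inside MspI sites read as partly methylated where their neighbours were unmethylated. In the 10520 windows that stayed low, MspI-site CpGs stood at 22.1% in WT, 21.9% in Fbxl10 T/T, 35.4% in Ring1B -/-, 34.0% in Eed -/- and 32.6% in Ezh2 -/-, against 1.60, 1.66, 3.15, 2.93 and 2.41% at the other CpGs. Incomplete conversion of whole libraries is ruled out by the lowest ratio of 11.2 between both kinds. The 3 MspI-site CpGs of the mitochondrial genome read at least 18.0%, and its 3 other CpGs at most 4.68%. This argues against methylation of nuclear CCGG sites as the only cause. With 3 positions outside the nucleus, it cannot tell whether part of the nuclear level is methylation. A read-end effect (end repair, base calls or trimming) may be the source, since the outer cytosine of the same sites also read at least 3.86 times higher than other CCG cytosines. Which of these steps is at work was not tested, and the added CpG-methylated control DNA was not analysed here.

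Windows below 10% in WT rose in Fbxl10 T/T in 2980 of 14323 cases. Incomplete conversion of the Fbxl10 T/T library is argued against by cytosines outside CpG, which read 0.688% there and 1.02% in WT, and different depth by the 2934 windows called after thinning to 10 reads. A minority of DNA from other cells (under 50%) is argued against by the 854 windows that rose by over 50 points with a lower bound above 60%. A difference between 2 lines or cultures other than the Fbxl10 genotype cannot be told apart from an effect of the genotype, with 1 library per genotype, and the extra reads of chromosome 6 show that both lines may differ in more than this gene. A loss of protection by FBXL10 is the biological explanation that the design names, and it stays open and untested.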

How the results depend on the processing

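Leaving out MspI-site CpGs (alone, at 5 reads or with summed reads), keeping them for the low windows, the authors' fraction, the low windows under all settings, the division of WT reads and the count without chromosome 6 were chosen after the data were seen. Of 329 counts and levels under alternatives, 144 stayed within 1.5 times of the main count or within its interval, 170 moved and 15 reversed. Intervals of levels are so narrow that most of them move. Of 916 values of named windows, 807 kept direction and call, 106 kept direction without the call and 3 reversed. All 244 values in Fbxl10 T/T kept both, as did 214 of 241 in Ring1B -/-, 193 of 236 in Eed -/- and 156 of 195 in Ezh2 -/-. These tallies are partly fixed by construction. The named windows are the largest calls, in Fbxl10 T/T rises of at least 75.8 points and falls from -72.2 to -65.7 points. The smallest named rises were 25.7 points in Ring1B -/-, 22.6 in Eed -/- and 20.03 in Ezh2 -/-, near the threshold. Autosomes only (76 of 76 kept) and at least 3 CpGs (77 of 77) leave the level of a named window as it is. The shares kept therefore do not compare how stable the mutants are. The 3 that reversed are those of chromosome 19, 42165001, in Ezh2 -/-, with -4.29 points at 5 reads, -18.0 without MspI-site CpGs at 5 reads and -13.5 with summed reads. The 15 others are the median differences of the Fbxl10 T/T gains in Ring1B -/-, Eed -/- and Ezh2 -/-, each below 0 in every setting without MspI-site CpGs. For Ezh2 -/- at 10 reads the interval of this value includes 0 (-0.817 to 0.528), and the highest of 20 divisions of the WT reads gave 0. Read-weighted means, windows of 2 kb and the authors' fraction left all counts within 1.5 times. The rise of low windows in Fbxl10 T/T moved by over 1.5 times only where MspI-site CpGs were kept or 10 CpGs were asked for. Where a setting admits other CpGs, windows or size thresholds, the counts change with it by construction, and otherwise the cause was not tested.

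No paired analysis was possible because each genotype has 1 library. Not run were strand positions kept apart, since CpGs are listed on 1 strand, every alternative for the fixed gene lists, since no annotation of build mm9 was used here, and a replicate block. Promoters of other length were replaced by windows of 2 kb. Depth limits the 3 Polycomb mutants most: at 10 reads they test 1972, 2255 and 1550 windows, against 27623 in Fbxl10 T/T. Values that moved or reversed follow by setting.

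At 5 reads per CpG, the level was 26.7% in WT, 32.1% in Fbxl10 T/T, 26.4% in Ring1B -/-, 25.8% in Eed -/- and 23.7% in Ezh2 -/-. Changed CpGs numbered 632 down in Ring1B -/-, 526 down in Ezh2 -/-. Changed windows numbered 193 up and 94 down in Ring1B -/-, 86 up and 107 down in Eed -/-, 64 up and 127 down in Ezh2 -/-. The median difference of Fbxl10 T/T gains was 3.67 in Ring1B -/-. Windows up in both numbered 103 in Ring1B -/-, 25 in Eed -/- and 19 in Ezh2 -/-. At 20 reads per CpG, the level was 25.9% in WT, 31.0% in Fbxl10 T/T, 32.3% in Ring1B -/-, 31.4% in Eed -/- and 24.5% in Ezh2 -/-. Changed CpGs numbered 87 up and 57 down in Ring1B -/-, 66 up and 39 down in Eed -/-, 26 up and 51 down in Ezh2 -/-. Changed windows numbered 1268 down in Fbxl10 T/T, 2 up and 2 down in Ring1B -/-, 3 up and 3 down in Eed -/-, 1 up and 3 down in Ezh2 -/-. The median difference of Fbxl10 T/T gains was 5.49 in Eed -/- and 1.48 in Ezh2 -/-. Shared gains numbered 1 in Ring1B -/- and 1 in Eed -/-. Without the CpGs of highest depth, the level was 26.9% in WT, 31.7% in Fbxl10 T/T, 22.2% in Ring1B -/-, 20.8% in Eed -/- and 19.4% in Ezh2 -/-. Changed windows numbered 6 down in Ezh2 -/-. In CpGs that reach the minimum in all 5 libraries, the level was 18.99% in WT, 30.7% in Fbxl10 T/T, 25.8% in Ring1B -/-, 26.4% in Eed -/- and 22.6% in Ezh2 -/-. Changed CpGs numbered 626 up and 136 down in Fbxl10 T/T, 129 up and 106 down in Ring1B -/-, 82 up and 71 down in Eed -/-, 72 up and 119 down in Ezh2 -/-. Changed windows numbered 23 up and 1 down in Fbxl10 T/T, 2 up and 2 down in Ring1B -/-, 4 up and 3 down in Eed -/-, 1 up and 5 down in Ezh2 -/-. The median difference of Fbxl10 T/T gains was 3.36 in Ring1B -/- and 3.30 in Ezh2 -/-. Windows up in both numbered 0 in Ring1B -/- and 0 in Eed -/-. On autosomes only, the level was 26.5% in WT, 31.9% in Fbxl10 T/T, 24.5% in Ring1B -/-, 23.0% in Eed -/- and 20.4% in Ezh2 -/-. Thinned to 10 reads per CpG, changed CpGs numbered 12604 up and 1970 down in Fbxl10 T/T, 4 up and 5 down in Ring1B -/-, 3 up and 10 down in Eed -/-, 0 up and 0 down in Ezh2 -/-. Changed windows numbered 17 up and 6 down in Ring1B -/-, 8 up in Eed -/-, 3 up and 5 down in Ezh2 -/-. Called up in both were 5 in Ring1B -/- and 1 in Eed -/-.

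At a difference of at least 10 points, changed windows numbered 3582 down in Fbxl10 T/T, 152 up and 18 down in Ring1B -/-, 131 up and 20 down in Eed -/-, 70 up and 17 down in Ezh2 -/-. Windows up in both numbered 35 in Ring1B -/-, 17 in Eed -/- and 9 in Ezh2 -/-. At a difference of at least 30 points, changed windows numbered 891 down in Fbxl10 T/T, 8 up and 4 down in Ring1B -/-, 3 up and 7 down in Eed -/-, 1 up and 6 down in Ezh2 -/-. Shared gains numbered 4 in Ring1B -/- and 1 in Eed -/-. At a difference of at least 40 points, changed CpGs numbered 21617 down in Fbxl10 T/T. With at least 3 CpGs per window, changed windows numbered 9984 down in Fbxl10 T/T, 110 up and 87 down in Ring1B -/-, 66 up and 64 down in Eed -/-, 36 up and 86 down in Ezh2 -/-. With at least 10 CpGs per window, changed windows numbered 3614 up and 104 down in Fbxl10 T/T, 3 up and 1 down in Ring1B -/-, 2 up and 0 down in Eed -/-, 0 up and 0 down in Ezh2 -/-. 1974 low windows rose in Fbxl10 T/T. After subtracting the median difference, changed windows numbered 17 up in Ring1B -/-, 11 up in Eed -/-.

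Without MspI-site CpGs, the level was 13.3% in WT, 20.6% in Fbxl10 T/T, 11.9% in Ring1B -/-, 11.5% in Eed -/- and 9.42% in Ezh2 -/-. Changed CpGs numbered 16011 down in Fbxl10 T/T, 137 up in Ring1B -/-, 61 up in Eed -/-, 29 up in Ezh2 -/-. Changed windows numbered 286 down in Fbxl10 T/T, 8 up and 4 down in Ring1B -/-, 7 up and 4 down in Eed -/-, 0 up and 5 down in Ezh2 -/-. The median difference of Fbxl10 T/T gains was -0.513 in Ring1B -/-, -0.758 in Eed -/- and -0.389 in Ezh2 -/-. Windows up in both numbered 3 in Ring1B -/- and 2 in Eed -/-. Without MspI-site CpGs and at 5 reads per CpG, changed windows numbered 354 down in Fbxl10 T/T, 50 up and 19 down in Ring1B -/-, 28 down in Eed -/-, 4 up and 28 down in Ezh2 -/-. The median difference of Fbxl10 T/T gains was -0.331 in Ring1B -/-, -0.972 in Eed -/- and -0.568 in Ezh2 -/-. Shared gains numbered 33 in Ring1B -/- and 3 in Ezh2 -/-. With reads outside MspI sites summed over windows of at least 30 reads, changed windows numbered 532 down in Fbxl10 T/T, 113 up and 48 down in Ring1B -/-, 32 up and 61 down in Eed -/-, 18 up and 67 down in Ezh2 -/-. The median difference of Fbxl10 T/T gains was -0.367 in Ring1B -/-, -0.977 in Eed -/- and -0.377 in Ezh2 -/-. Called up in both were 78 in Ring1B -/-, 10 in Eed -/- and 8 in Ezh2 -/-. Without MspI-site CpGs and with WT reads divided between the comparisons, the median difference of Fbxl10 T/T gains was -0.488 in Ring1B -/-, -0.780 in Eed -/- and -0.249 in Ezh2 -/-. Windows up in both numbered 3 in Ring1B -/- and 2 in Eed -/-. With summed reads and WT reads divided, the median difference of Fbxl10 T/T gains was -0.342 in Ring1B -/-, -0.943 in Eed -/- and -0.411 in Ezh2 -/-. Shared gains numbered 75 in Ring1B -/-, 10 in Eed -/- and 8 in Ezh2 -/-. With MspI-site CpGs kept, 1818 low windows rose in Fbxl10 T/T.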

Other observations

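The level reached by the risen windows lies well short of full methylation, with a median of 57.5% in Fbxl10 T/T. In Fbxl10 T/T the window on chromosome 5 from 144014001 stood at 89.2%, and in the same stretch the window from 144016001 was the largest gain of Ring1B -/- (78.7%). Of the gains of Ring1B -/- in windows with summed reads, 78 of 113 were gains of Fbxl10 T/T as well, and so were 10 of 32 in Eed -/- and 8 of 18 in Ezh2 -/-, without a test of the difference between the mutants. Independent lists give 24.2, 7.05 and 3.85, which is too low a scale because it takes no account of the WT level. With summed reads Eed -/- gave 4 windows up and 58 down against Ring1B -/-, Ezh2 -/- gave 1 up and 63 down against Ring1B -/-, and Ezh2 -/- gave 5 up and 19 down against Eed -/-.

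Without MspI-site CpGs, 7.95% of the 370743 CpGs covered in Fbxl10 T/T stood above 80%, and 12.4% of the 403914 covered in WT, while 60.2% and 75.1% stood below 10%. Both shares are over the CpGs that each library covers. Other clusters of risen windows lay on chromosome 9, 62990001 to 62998000 (4.37 to 68.6%), on chromosome 7, 138685001 to 138701000 (2.57 to 67.1%), and on X, 11705001 to 11738000 (3.57 to 53.0%).

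Chromosome Y held 41003 of 137051589 reads in WT, 11166 of 88451884 in Fbxl10 T/T, 2680 of 6020913 in Ring1B -/-, 2380 of 6249001 in Eed -/- and 2407 of 5761972 in Ezh2 -/-. Reads on X stood at 0.987, 0.989, 0.994 and 1.14 times WT in Fbxl10 T/T, Ring1B -/-, Eed -/- and Ezh2 -/-. Cytosines followed by AC read 2.47% in WT and 1.21% in Fbxl10 T/T.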
